A study of Mus musculus with 3 samples.

How the data were processed

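Gene expression was measured on single-colour Affymetrix arrays in 3 samples of YFP-positive cells, sorted from the kidney cortex of adult male mice given captopril and low-salt chow. Per the labels, RNA was amplified in 1 round with a NuGEN kit and labelled with biotin, and samples were not pooled. The deposited values are 1 log2 signal per probe set and array. Affymetrix Expression Console is named in the submitters' processing notes, and its version, summary method, background correction and normalization are not given in the sources used here. The log2 scale was inferred from the values, which ran from 2.21 to 13.96 with medians of 6.09, 6.11 and 6.21, and no source states the log base. The arrays' distributions were close without being identical, so some normalization between arrays is assumed to have been applied before deposit. The number of arrays, 3, limits the precision. Probe affinity also sets a signal, so levels were read against background and over lists, and where genes were picked by mean signal their order does not rank abundance.

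Probe sets were named from the platform's annotation table. Of 35557 probe sets, 21789 had 1 gene symbol, 1621 several and 12147 were not listed there and stay unnamed here. Symbols were checked through Entrez identifiers against a RefSeq table of assembly GRCm38.p6, which matched 21698 of the 21789 probe sets and changed 0 symbols. That table was used for names only, and no coordinates are given because the array's build is not named. Probe sets with several symbols were left out. For the 999 genes with more than 1 probe set the brightest was taken, since a gene is under background only if all its probe sets are. This left 19938 genes.

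The background level of an array was the 95th percentile of its log2 signals over 1027 olfactory receptor genes, a family not taken to be used in these cells, and came to 6.20, 6.32 and 6.50 in replicates 2, 4 and 5. The log2 signal minus this level was fitted with limma 3.58.1 in R 4.3.3 (intercept only, eBayes with a trend), and a one-sided test asked whether the mean was above 0, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Families that do not set the level checked the rate: 2 of 169 vomeronasal receptor genes were called (1.18%, exact 95% interval 0.144 to 4.21) and 10 of 44 keratin-associated protein genes (22.7%, exact 95% interval 11.5 to 37.8). Of the olfactory receptor genes themselves 21 (2.04%) were called. At an unadjusted p under 0.05, 8086 genes passed.

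Before the data were examined, 41 gene lists were fixed: renin cell genes, the renin-angiotensin system, signalling, secretion, metabolism and stress lists, housekeeping genes, and markers of kidney, blood, fat, adrenal and nerve cells. They hold 548 symbols, of which 490 were measured and 58 were not used here, and 27 genes stand on more than 1 list. For each list the members above background were counted, with p adjusted over all genes and over the list alone, and the list's median was placed among 10000 random lists of the same size. For each array and each of the 30 lists with at least 3 called members, the shift was the median over called members of that array minus the mean of the other 2, placed among 10000 random lists drawn from the same 20 signal bins. These percentiles describe the arrays and give no p. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

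The genes named in the text were chosen by a rule fixed beforehand. It takes every member of the renin cell and renin-angiotensin lists, up to 4 brightest called members and the lowest member of each other list, and the 15 genes with the highest mean. It adds, per array, the 5 called genes furthest above and the 5 furthest below the other arrays. Ribosomal, mitochondrial-genome and unnamed predicted genes were left out of the last parts. The pattern for mitochondrial-genome names was widened, after the values were seen, to names without the mt prefix. Some members of the longer lists were left out for length, and these were not always the dimmest. Hk1 (12.22), Ldhb (11.61) and Cox5b (12.81) were left out, while dimmer genes of glycolysis and oxidative phosphorylation were named. The other probe set of Hk1 had a mean of 7.05.

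The test was checked on simulated arrays of 19938 genes with 200 genes planted at known heights. It called 80.0%, 94.0%, 100% and 100% of genes planted 0.5, 1, 2 and 3 log2 units above the level, and 0.191% of genes simulated at or under it. The simulation held only noise between arrays, so this rate does not cover probes whose background signal lies above the level. For list shifts, 100 lists of 10 genes among 7437 were raised by 0, 0.3 or 0.6, and 5.0%, 45.0% and 98.0% lay outside the central 95% of matched random lists. The fixed lists had other sizes, down to 3 called members, and their members can vary together. These rates therefore need not carry over to them. The alternatives tried were other percentiles and families for the background level, quantile normalization and median-centring of the arrays, the mean of a gene's probe sets, probe sets with several symbols kept, eBayes without the trend, a filter on dim genes, leaving out each replicate, a plain rule in place of the test, all list members in place of called members, and other random lists. Leaving out shared list members, the keratin-associated background, the second marker lists over all measured members, and a comparison of the weighed lists with 1 other array alone were added after the data were seen. There was 1 group and no control, so no comparison between conditions was made.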

Results

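Renin-producing cells were profiled from the kidneys of adult male Ren1c-YFP transgenic mice, in which these juxtaglomerular cells carry yellow fluorescent protein (YFP). The mice had received captopril, an inhibitor of angiotensin-converting enzyme, at 0.5 mg/ml in their water, and low-salt chow, for 2 weeks. This combination is known to raise renin production. Cortex was digested, YFP-positive cells were collected by fluorescence-activated sorting, and their amplified RNA was hybridised to single-colour Affymetrix arrays. The series holds 1 group of 3 arrays, replicates 2, 4 and 5. No untreated, unsorted or YFP-negative sample was analysed here, so the values describe levels in the sorted samples and not an effect of captopril, of salt or of the sort. The labels state that samples were not pooled but do not say outright that each came from a separate animal, so p-values measure only the spread between these samples. Median log2 signals over all 35557 probe sets were 6.09, 6.11 and 6.21 in replicates 2, 4 and 5.

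The first question was which transcripts were measured above background in the sorted cells. Most measured genes of the renin cell and of contractile mural cells, and all of those of protein folding and mitochondrial respiration, were above background, together with markers of the kidney tubule. Of 11 measured renin cell genes, out of 16 listed, 10 passed the test. So did 14 of 16 smooth muscle genes, 19 of 19 proximal tubule markers and 8 of 8 thick ascending limb markers. No lymphocyte, neutrophil, erythroid or nerve marker passed (0 of 12, 0 of 9, 0 of 4 and 0 of 8). In all, 7437 of 19938 genes (37.3%) were above background by limma's one-sided test, against a level set for each array by its olfactory receptor genes.

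Among the renin cell genes, Rgs5, a regulator of G protein signalling in mural cells, had a log2 signal of 12.37 ± 0.10 (mean ± SD, n = 3 here and below), 6.03 above background. Crip1, a LIM domain protein, stood at 11.95 ± 0.18, and Gja5, which encodes the gap junction protein connexin 40 of renin cells, at 11.34 ± 0.32. The other connexin genes of the list were Gja4 (8.15 ± 0.85) and Gjc1 (7.75 ± 0.60). Pde3a, a phosphodiesterase that cGMP inhibits, had a signal of 9.01 ± 0.19, and Agtr1a, the type 1 angiotensin II receptor, one of 8.66 ± 0.32. Rbpj, the transcription factor at the end of the Notch pathway, was at 7.99 ± 0.08, Atp6ap2, the prorenin receptor, at 7.95 ± 0.26, and Npr1, a natriuretic peptide receptor, at 7.58 ± 0.25. Ace, the gene of captopril's target enzyme, had a mean 0.40 above background and did not pass (6.75 ± 0.42, limma adjusted p = 0.109 over all genes). With p adjusted over the list alone, all 11 passed. With the background at the 99th percentile of olfactory receptor genes, Gja4, Gjc1 and Npr1 missed the threshold (limma adjusted p = 0.0868, 0.177 and 0.195), as did Rbpj with the mean of its probe sets (limma adjusted p = 0.130). The list's median lay at percentile 99.8 of 10000 random lists of the same size, and 10 of its 11 members also stand on other lists. The fixed list held 16 genes, of which Ren1, Ren2, Akr1b7, Adrb1 and Adora1 were not analysed here. Renin's own transcript is thus not among these values, and the count of 10 of 11 does not by itself identify renin cells.

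Of 10 measured members of the renin-angiotensin system, 4 passed, also when adjusted over the list alone. They were Agtr1a, Atp6ap2 and the peptidase genes Enpep (10.01 ± 0.18), whose product cleaves angiotensin II, and Mme (8.62 ± 0.42), which encodes neprilysin. Agt, the gene of angiotensinogen, did not pass (6.68 ± 0.13, limma adjusted p = 0.0727) and nor did Ace. The second angiotensin receptor gene Agtr2 (5.64 ± 0.59), the Mas1 receptor gene (5.45 ± 0.22) and the mast cell proteases Cma1 (5.25 ± 0.12) and Cpa3 (4.28 ± 0.06) had means under the background level. The list's median lay at percentile 75.8 of random lists.

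Signalling lists that control renin release were above background for most members, in samples that also carried tubule and endothelial transcripts. Over all fixed lists together 304 of 490 measured members passed (62.0%), so a share near that does not set a list apart. A call above background does not say which cells of a sample the transcript came from. In the list for cAMP, the main stimulus of renin release, 16 of 23 members passed, among them Calcrl (9.93 ± 0.51), Crebbp (9.79 ± 0.63) and Prkar1a (9.36 ± 0.15), while Pde1c (5.55 ± 0.28) did not. For cGMP and natriuretic peptides 6 of 11 passed, among them Gucy1a1 (9.31 ± 0.12), a subunit of soluble guanylate cyclase, and the kinase genes Prkg2 (8.47 ± 0.86) and Prkg1 (8.05 ± 0.62). For calcium and angiotensin II 15 of 20 passed, with Rgs2 at 10.64 ± 0.26, Ednrb at 9.70 ± 0.41 and Gna11 at 9.47 ± 0.46, and Kcnma1 (5.28 ± 0.09) under the level. Of 8 gap junction genes 5 passed, Gjb2 (8.74 ± 0.83) in addition to those named, and Gjd2 (5.32 ± 0.38) did not. In the Notch pathway 13 of 16 passed, with Jag1 at 9.27 ± 0.61, Hey2 at 9.07 ± 0.45, Heyl at 8.66 ± 0.44 and Notch3 at 8.55 ± 0.12, and without replicate 2 the count fell to 8. Among stromal and mural transcription factors 17 of 26 passed (19 adjusted over the list alone), including Epas1 (10.88 ± 0.50), Hoxd8 (9.64 ± 0.35), Nr2f2 (9.29 ± 0.13) and Foxc2 (9.23 ± 0.46), and Tbx18 (4.74 ± 0.32) did not. The counts adjusted over the list alone were otherwise those given, for these lists and for the rest except where stated. In the order given, the medians of these lists lay at percentiles 99.4, 97.8, 100, 94.4, 95.6 and 98.6 of random lists.

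Contractile, pericyte and mesangial genes were above background for most members. Acta2, smooth muscle actin, was at 12.62 ± 0.06, Myl9, a myosin light chain, at 12.40 ± 0.07, Myh11, smooth muscle myosin, at 11.98 ± 0.36 and Cald1, caldesmon, at 11.76 ± 0.18. Actg2 (6.14 ± 0.17) did not pass. Of 12 pericyte markers 9 passed, Mcam (10.21 ± 0.40) and Abcc9 (8.14 ± 0.03) among them, and Higd1b (5.63 ± 0.41) did not. Of 8 mesangial markers 7 passed, with Igfbp5 at 10.79 ± 0.60, Gata3 at 8.68 ± 0.26 and Itga8 at 8.12 ± 0.29, and Thy1 (6.20 ± 0.17) did not. Fibroblast markers passed in 5 of 12 cases, Cd248 (9.23 ± 0.45), Col1a2 (7.81 ± 0.20) and Col1a1 (7.78 ± 0.03) among them, and Lum (4.11 ± 0.09) was far under the level. The list medians lay above all 10000 random lists for smooth muscle, and at percentiles 99.5, 98.6 and 27.1 for pericyte, mesangial and fibroblast genes.

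Protein folding, lysosomal, respiratory and housekeeping genes were above background in all measured members. All 20 genes of protein folding in the endoplasmic reticulum passed, with the chaperone genes Hsp90b1 at 12.88 ± 0.01 and Canx at 12.34 ± 0.04 and Xbp1 at 7.78 ± 0.26. All 19 lysosome and dense granule genes passed, among them Cd63 (13.12 ± 0.02), Ctsb (11.99 ± 0.06) and Lamp2 (11.34 ± 0.28), and Lyst (7.01 ± 0.19) lost its call without replicate 2 and without replicate 4 (limma adjusted p = 0.0724 and 0.0772). Regulated secretion genes passed in 9 of 17 cases, including Cpe (11.22 ± 0.07), a prohormone carboxypeptidase, Stx4a (10.04 ± 0.50) and Snap23 (10.04 ± 0.45), and Cadps (4.87 ± 0.14) did not. All 25 genes of oxidative phosphorylation passed, with Cox6c at 12.93 ± 0.04 and Atp5b at 12.50 ± 0.06, as did 10 of 12 glycolysis genes, with Pgk1 at 11.80 ± 0.14 and Aldoa at 11.50 ± 0.18, and Hk2 (5.46 ± 0.05) under the level. All 13 housekeeping genes passed, and Tbp (7.09 ± 0.33) did not pass without replicate 2 (limma adjusted p = 0.0941). The medians of these lists lay above all random lists, except that of regulated secretion at percentile 85.4.

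Further lists were mixed. Of 12 prostaglandin genes 2 passed, Ptges3 (11.83 ± 0.12) and Ptgis (7.76 ± 0.25), and without replicate 5 there were 6, while Ptger2 (5.71 ± 0.17) was under the level. Angiogenic factors passed in 9 of 16 cases, among them Angpt2 (9.19 ± 0.21), Pdgfa (8.33 ± 0.23) and Vegfb (8.25 ± 0.21), and hypoxia response genes in 9 of 14, with Ndrg1 at 11.10 ± 0.79, Egln3 at 9.86 ± 0.15 and Hif1a at 9.65 ± 0.11. The erythropoietin gene Epo (4.67 ± 0.18) and Hgf (5.05 ± 0.16) were under the level. Cell cycle genes passed in 4 of 18 cases, namely Pcna (10.15 ± 0.33), Ccnd1 (8.89 ± 0.37), Mcm6 (7.08 ± 0.28) and Mcm2 (7.04 ± 0.02), and Bub1 (4.54 ± 0.16) did not. Mcm6 lost its call without replicate 2 (limma adjusted p = 0.0829). Of 13 interferon response genes 4 passed, Ifit3 (8.22 ± 1.70), Bst2 (7.75 ± 0.47), Usp18 (7.34 ± 0.30) and Irf1 (6.99 ± 0.73), and Mx1 (3.68 ± 0.13) did not. Without replicate 2 the interferon count was 2, since Ifit3 and Irf1 then missed the threshold (limma adjusted p = 0.103 and 0.0967), and Irf1 also missed it without replicate 5 (limma adjusted p = 0.153). Immediate early and dissociation response genes passed in 13 of 21 cases (14 adjusted over the list alone), with Ccn1 at 9.63 ± 0.82, Hspa1a at 9.15 ± 0.58 and Dusp1 at 8.79 ± 0.65, and Atf3 (5.83 ± 0.11) under the level. In the order given, the list medians lay at percentiles 73.1, 98.4, 98.98, 42.3, 71.4 and 99.4.

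Markers of other kidney cells were also measured in these samples, although the cells had been gated on YFP. The proximal tubule genes included Kap (13.09 ± 0.08), the androgen-regulated kidney protein, Gpx3 (12.69 ± 0.27), Slc27a2 (12.25 ± 0.15) and Gatm (11.41 ± 0.38), and Slc22a12 stood at 7.55 ± 0.17. In the thick ascending limb list, Umod, uromodulin, was at 11.79 ± 0.57, Kcnj1 at 10.90 ± 0.32 and the salt transporter gene Slc12a1 at 10.44 ± 0.82. Distal convoluted and connecting tubule markers passed in 5 of 7 cases, with S100g at 11.85 ± 0.56, Calb1 at 9.17 ± 0.14 and Slc12a3 at 9.09 ± 0.42, and Pvalb (5.40 ± 0.37) did not. Principal cell markers passed in 7 of 9 cases, with Fxyd4 at 8.59 ± 0.82, Scnn1g at 8.29 ± 0.75 and Aqp2 at 8.23 ± 0.23, and Aqp4 (5.68 ± 0.13) did not. All 8 intercalated cell markers passed, Atp6v1g3 (11.09 ± 0.23) and Slc4a9 (8.47 ± 0.51) among them, and 5 did without replicate 4, Aqp6 (6.82 ± 0.33) losing its call there and without replicate 2 (limma adjusted p = 0.266 and 0.0594). Macula densa markers passed in 1 of 5 cases, Avpr1a (7.36 ± 0.37), and in 2 without replicate 5, with Oxtr (5.91 ± 0.28) under the level. Podocyte markers passed in 2 of 7, Plce1 (8.0 ± 0.32) and Cdkn1c (7.76 ± 0.43), and not in Ptpro (5.34 ± 0.41). Of 14 endothelial markers 8 passed, with Emcn at 9.22 ± 0.56, Flt1 at 7.58 ± 0.97, Pecam1 at 7.56 ± 1.27 and Cdh5 at 7.46 ± 1.10. The endothelial count was 2 without replicate 2, where Pecam1 and Cdh5 missed the threshold (limma adjusted p = 0.120 and 0.162), and 5 without replicate 4. The proximal tubule and thick ascending limb medians lay above all random lists, and those of the distal, principal cell, intercalated, macula densa, podocyte and endothelial lists at percentiles 99.04, 96.2, 95.8, 47.3, 59.6 and 85.9.

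Blood, fat, adrenal and nerve markers were mostly under the background level. Macrophage and dendritic markers passed in 3 of 16 cases (2 adjusted over the list alone), H2-Aa (7.68 ± 0.56), Cx3cr1 (7.65 ± 0.33) and Tyrobp (6.73 ± 0.19), and Tyrobp did not pass without replicate 2, 4 or 5 (limma adjusted p = 0.115, 0.205 and 0.0792). The lymphocyte, neutrophil, erythroid and nerve markers named by the rule were Cd79a (4.29 ± 0.24), Mmp8 (3.99 ± 0.16), Rhag (4.17 ± 0.10) and Dbh (5.17 ± 0.25). Of 7 adipocyte markers 1 passed, the glucose transporter gene Slc2a4 (7.68 ± 0.30), and Adipoq (4.05 ± 0.08) did not. Of 9 adrenal steroidogenic markers 1 passed, Fdx1 (10.70 ± 0.19), which encodes a mitochondrial ferredoxin, and Hsd3b1 (3.89 ± 0.06) did not. Of 3 measured Y-linked genes, Eif2s3y (7.68 ± 0.36) and Kdm5d (7.04 ± 0.14) passed and Uty (6.76 ± 0.26) passed only when adjusted over the list alone, while the female-specific Xist (4.98 ± 0.02) was under the level, in samples labelled male. Kdm5d was not called without replicate 2 or without replicate 4 (limma adjusted p = 0.0582 and 0.0581), Uty was called without replicate 5 (limma adjusted p = 0.0248), and the Y-linked count was then 1, 1 and 3. The medians of the macrophage, lymphocyte, neutrophil, erythroid, adipocyte, adrenal, nerve and Y-linked lists lay at percentiles 10.9, 10.7, 0.23, 13.2, 21.4, 3.63, 12.9 and 76.1, and the single gene Xist at 16.4.

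**Figure D1:**
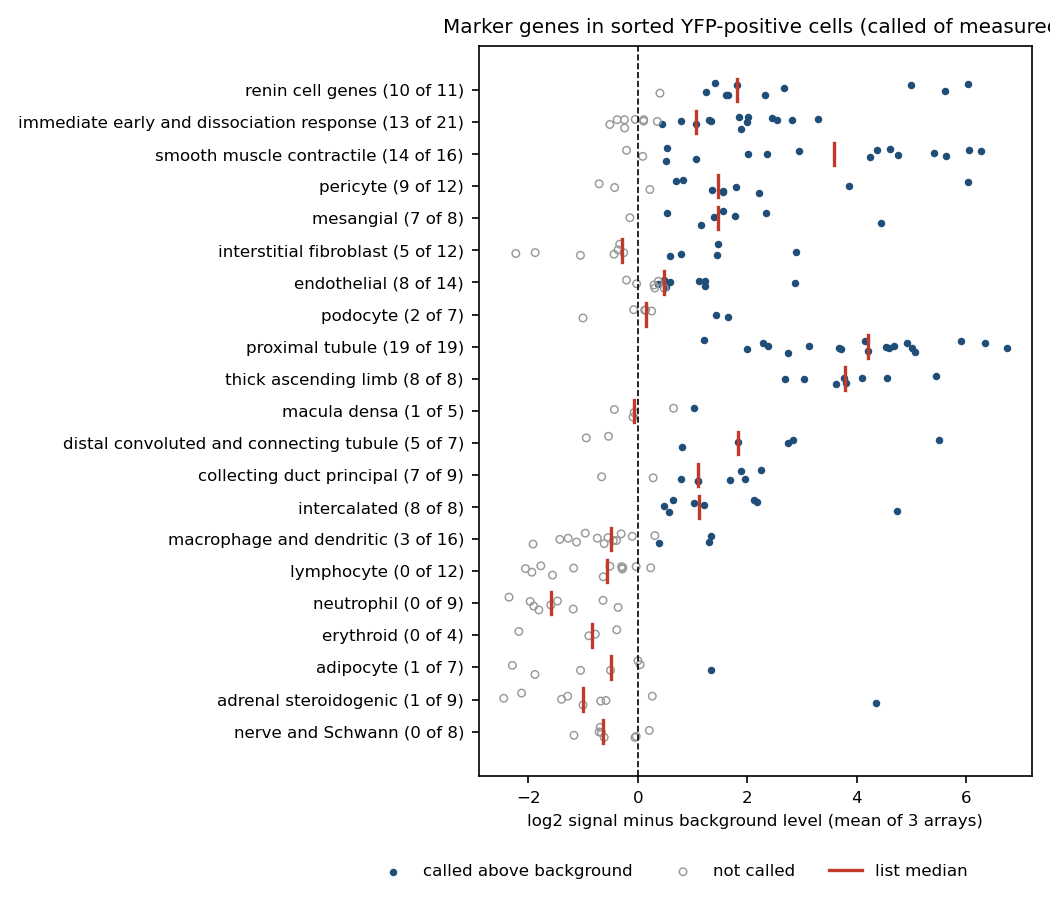
Each point is a gene of a fixed list, placed by its mean log2 signal over 3 arrays minus the background level (dashed line at 0), filled where limma's test called it, with the list median as a red bar and called over measured counts beside each name. All 19 proximal tubule and 8 thick ascending limb markers and 10 of 11 renin cell genes were called, against 0 of 12 lymphocyte and 0 of 9 neutrophil markers, and a point's height also depends on its probes.

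The naming rule also picked 15 genes by their mean signal, apart from ribosomal, mitochondrial-genome and unnamed genes. Which genes it picked depends in part on probe affinity and on the probe set taken, so they are given by name and not as a ranking. They were Actb (13.04 ± 0.05), Baiap2l1 (13.40 ± 0.07), Calm2 (13.01 ± 0.06), Cd63, Cox6c, Eef1a1 (13.26 ± 0.06), Gas5 (13.06 ± 0.03), Hsp90b1, Itm2b (12.98 ± 0.06), Kap, Malat1 (12.97 ± 0.15), Mgp (13.27 ± 0.02), Myl6 (13.12 ± 0.08), Sparcl1 (13.01 ± 0.15) and Tpt1 (13.29 ± 0.04). Mgp encodes matrix Gla protein, an inhibitor of vessel calcification. Probe sets of a gene can disagree: those of Baiap2l1 had means of 13.40, 11.40 and 5.85, and those of Gas5 means of 13.06, 9.03, 6.46 and 6.38. Whether the annotation pairs each of these probe sets with the right gene was not checked, so the values are those of the probe sets taken and need not be the levels of Baiap2l1 and Gas5. Of 688 called genes with more than 1 probe set, 364 had probe sets more than 1 log2 unit apart and 187 had a probe set under the level.

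The number of genes called rested on the level taken as background. It was 3303 at the 99th percentile of olfactory receptor genes in place of the 95th, 13165 with a level from vomeronasal receptor genes and, in a check added later, 709 with one from keratin-associated protein genes, and the test's error covers the spread between arrays but not that between background probes.

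The second question was how far the 3 samples differed from each other. Across the 19938 genes the arrays correlated at Pearson r = 0.972 (replicates 2 and 4), 0.964 (2 and 5) and 0.962 (4 and 5), with Spearman rho of 0.965, 0.953 and 0.951, and genes are not independent replicates. The median SD of a called gene was 0.27 on the log2 scale. The difference between the highest and lowest array exceeded 1 log2 unit in 1022 of the 7437 called genes (13.7%).

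The 5 called genes furthest above the mean of the other arrays in replicate 2 were Heg1 (2.41 log2 units), Ptprb (2.40), Pecam1 (2.20), Adgrl4 (2.19) and Srgn (2.17), of which Ptprb encodes a receptor phosphatase and Pecam1, a member of the endothelial list, an adhesion molecule. Those furthest below in replicate 2 were Spink8 (-2.31), Ociad2 (-2.10), Mir681 (-1.81), Cyp4a31 (-1.73) and Tmem185a (-1.67). In replicate 4, Ifit3 (1.96), Spa17 (1.91), Mir681 (1.80), Larp1 (1.76) and Trps1 (1.63) were furthest above, and Mpp7 (-2.12), Hmcn1 (-2.01), Ptprb (-1.80), the endothelin gene Edn1 (-1.77) and the potassium channel gene Kcna5 (-1.69) furthest below. In replicate 5, Ociad2 (1.49), Vmn2r-ps104 (1.47), Zfp938 (1.44), Fbxl20 (1.43) and Uprt (1.42) were furthest above, and Ifit3 (-2.88), Car4 (-2.52), Uxt (-2.45), Tmx2 (-2.38) and Leprot (-2.28) furthest below. Each value sets a single array against the mean of the others, so none has a test. For Hmcn1 it is that of the brightest of many probe sets, whose means ran from 7.47 down to 3.06. With the mean of its probe sets, Hmcn1 lay at -1.39 against the background level. Some of these genes were called above background with the help of 1 array: Adgrl4, Srgn, Edn1 and Hmcn1 missed the threshold without replicate 2 (limma adjusted p = 0.0581, 0.0637, 0.119 and 0.162), and Hmcn1 and Vmn2r-ps104 without replicate 5 (limma adjusted p = 0.0941 and 0.0521). The count of genes with a range over 1 was 477 with the background at the 99th percentile of olfactory receptor genes. It lay between 299 and 588 with an array left out, since the range of 2 values is smaller by construction.

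The third question was whether whole lists were higher or lower on 1 array. Endothelial markers were higher in replicate 2 than in the others by a median of 0.77 log2 units over 8 called members, 7 of them higher. The endothelial calls themselves leaned on that array, since 2 of 14 markers were called without it, and over all 14 measured markers the shift was 0.56 (percentile 100 of random lists matched on signal). Principal cell and intercalated markers were lower there, by medians of -0.76 (7 of 7 called members, and -0.52 over all 9 measured) and -0.37 (8 of 8). Proximal tubule and thick ascending limb markers were lower in replicate 5, by -0.57 (17 of 19) and -0.86 (8 of 8). Smooth muscle genes were lower in replicate 4 by -0.28 (13 of 14) and renin cell genes by -0.20 (9 of 10). Higher there were markers of the proximal tubule (0.33, 16 of 19), thick ascending limb (0.64, 7 of 8), principal cells (0.60, 7 of 7) and intercalated cells (0.42, 7 of 8). Proximal tubule markers in replicate 4 lay 0.66 above replicate 5 alone (percentile 99.99). For these markers replicate 2 minus replicate 4 was -0.15 (percentile 0.5), with 11 of 19 lower in replicate 2. Much of the 0.33 thus came from the low replicate 5. Set against replicate 5 alone, principal cell markers in replicate 4 were 0.52 higher (percentile 89.63) and intercalated markers 0.08 (percentile 48.0). Both lay inside the central 95%, and the intercalated value came mostly from the low replicate 2. Against 1 array alone, endothelial markers in replicate 2 were 0.71 above replicate 4 and 0.83 above replicate 5, and principal cell markers -1.27 and -0.46 against the same arrays. Over all measured members these values were 0.55 and 0.51 for endothelium and -0.57 and -0.23 for principal cells, so the rise in replicate 4 took part in the lower value of replicate 2. Proximal tubule markers in replicate 5 were -0.48 against replicate 2 (percentile 3.81) and -0.66 against replicate 4. A second proximal tubule list of 22 measured genes was 0.17 higher in replicate 4 (percentile 85.55, inside the central 95%) and 0.55 higher in replicate 2 (percentile 100), where the first list stood at 0.23 (percentile 76.9). On the second list replicate 2 minus replicate 4 alone was 0.17 (percentile 88.83), with 15 of 20 called members higher in replicate 2.

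Among signalling and stress lists in replicate 2, cAMP genes were higher by 0.52 (15 of 16), connexins by 0.72 (4 of 5), Notch pathway genes by 0.41 (12 of 13) and immediate early and dissociation genes by 0.66 (10 of 13), on the array with the higher endothelial markers. Over all measured members the cAMP shift was 0.25 (percentile 96.9) and the Notch shift 0.26 (percentile 94.65), inside the central 95% of matched random lists, and that of immediate early genes 0.43 (percentile 99.9). The connexin genes included Gja4 (1.45 higher there) and Gja5 (0.54), the Notch genes Jag1 (1.00) and Heyl (0.77), and the immediate early genes Ccn1 (1.37) and Dusp1 (0.93). Distal tubule markers (-0.33, 5 of 5) and macrophage markers (-0.54, 3 of 3 called, and -0.22 over all 16 measured) were lower in replicate 2. In replicate 4, where the tubule lists named above were higher than the mean of the other arrays, the endothelial list was lower (-0.35, 7 of 8). That value came from the high replicate 2, since endothelial markers in replicate 4 lay 0.03 above replicate 5 alone (percentile 52.95). Also lower in replicate 4 were cGMP genes (-0.47, 4 of 6), with Prkg2 at -1.32 and Prkg1 at -1.07. So were calcium and angiotensin II genes (-0.17, 9 of 15), Notch genes (-0.23, 10 of 13) and immediate early genes (-0.19, 9 of 13). Of these, the calcium and angiotensin II shift was -0.0080 without members shared with other lists (percentile 20.25) and lay at percentile 3.11 after quantile normalization. The Notch and immediate early shifts lay at percentiles 5.19 and 2.55 over all measured members. In replicate 5 the endothelial list was lower (-0.53, 7 of 8, and -0.33 over all measured members). This too came from replicate 2, since replicate 5 lay level with replicate 4 on that list. Distal tubule (0.53, 3 of 5), intercalated (0.20, 6 of 8), cGMP (0.23, 5 of 6) and pericyte genes (0.14, 5 of 9) were higher in replicate 5. Each of these 4 higher lists came inside the central 95% under some alternative. Over all measured members the distal tubule shift was 0.12 (percentile 91.6), and with the mean of a gene's probe sets it was 0.28. The pericyte shift was -0.049 over all 12 measured markers instead of the 9 called (percentile 73.05), and the cGMP shift was 0.080 over all 11 (percentile 81.7). The intercalated shift lay at percentile 94.85 after quantile normalization.

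These 27 of 90 list shifts lay outside the central 95% of 10000 random lists matched on signal. By chance 4.5 would, if members of a list varied like genes drawn separately. Members of a marker list can vary together, so the excess over 4.5 is not a test. Lists share members and the shifts of 3 arrays sum to about 0, so they are not independent, and each rests on 1 sample and has no p. Of the 27, 17 stayed outside under every alternative counted for them. Comparisons with 1 array alone were counted only for the patterns weighed below. As given above, endothelial markers in replicates 4 and 5 came inside against 1 array alone. So did principal cell and intercalated markers in replicate 4. All of these shifts are among the 17. The signals of replicate 5 spanned a narrower range (SD over genes 1.58, against 1.75 and 1.71 in replicates 2 and 4), and the brightest 25% of called genes lay at -0.31 against the other arrays there, which the matching on signal takes into account.

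**Figure D2:**
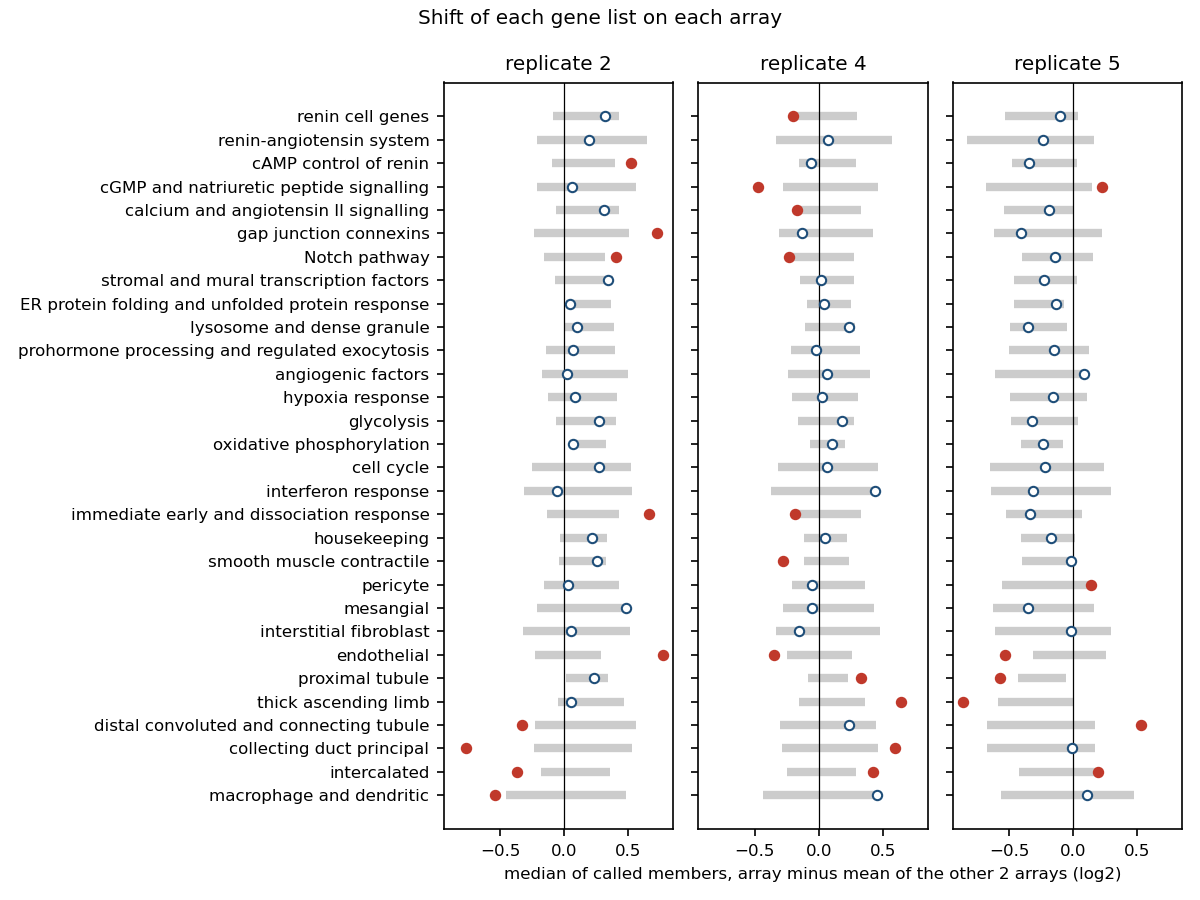
Each point is the median, over the called members of a list, of the log2 signal on 1 array minus the mean of the other 2 arrays, in a panel per replicate, with grey bars for the median ± 2 SD of signal-matched random lists and red points for shifts outside their central 95%. Endothelial markers stood 0.77 above in replicate 2, and thick ascending limb markers -0.86 below 0 in replicate 5.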

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

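The values here were computed as counts with no test, and no explanation was tested for them. Signal also appeared in probe sets outside the report's comparisons. Of the 12147 probe sets that the annotation used here does not list, 3427 (28.2%) lay above the background level on all 3 arrays, and some of them can be control probe sets of the array. Of the 1621 probe sets with several gene symbols, 806 (49.7%) lay above the level on all 3 arrays. For genes with 1 symbol that plain rule gave 8360 of 19938.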

How the results depend on the processing

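The tests with a background from keratin-associated protein genes, those without shared list members, those against 1 other array alone and those over all members of the second lists were chosen after the results were seen. No paired analysis was possible because there is 1 group. Of 202 named genes, 144 kept the same call under every alternative run for them, which did not include the keratin-associated background. Median-centring cannot change which genes are above background, since it moves an array and its level together. The cause of the changes below was not tested, except that a level set higher or lower calls fewer or more genes by construction and that 2 arrays give a smaller range than 3. Signal over background limits the calls for genes near the level.

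The count of 7437 genes above background was 3303 at the 99th percentile of olfactory receptor genes, 13165 with vomeronasal receptor genes and 709 with keratin-associated protein genes. Under the other alternatives it lay between 6051 and 9964, and all 3303 genes of the strictest planned level were among the 7437. The count of genes with a range over 1 was 477 at the 99th percentile and 299 to 588 with a replicate left out.

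At the 99th percentile, list counts fell to 10 for cAMP, 2 for connexins, 6 for Notch, 10 for stromal transcription factors, 5 for regulated secretion, 1 for prostaglandins, 5 for angiogenic factors, 2 for cell cycle, 0 for interferon, 8 for immediate early genes, 5 for pericytes, 3 for mesangial cells, 2 for fibroblasts, 1 for endothelium, 1 for podocytes, 0 for macula densa, 3 for principal cells, 3 for intercalated cells, 0 for macrophages, 0 for adipocytes and 0 for Y-linked genes. At the 90th percentile they were 9 for prostaglandins, 7 for cell cycle, 13 for endothelium, 5 for podocytes, 2 for macula densa, 2 for lymphocytes, 3 for adipocytes, 2 for adrenal and 3 for nerve. With vomeronasal receptor genes they were 10 for cGMP, 11 for prostaglandins, 15 for angiogenic factors, 13 for cell cycle, 8 for interferon, 21 for immediate early genes, 9 for fibroblasts, 14 for endothelium, 6 for podocytes, 5 for macula densa, 10 for macrophages, 6 for lymphocytes, 1 for neutrophils, 1 for erythroid cells, 4 for adipocytes, 2 for adrenal and 3 for nerve. The plain rule gave 5 for prostaglandins, 1 for lymphocytes and 2 for adrenal, and the dim filter 4 for prostaglandins. The endothelial count was 5 without the trend and 4 with several-symbol probe sets kept. With a replicate left out, the counts ranged from 8 to 13 for Notch, 2 to 5 for interferon, 2 to 10 for endothelium, 5 to 8 for intercalated cells, 2 to 6 for prostaglandins, 1 to 2 for macula densa and 1 to 3 for Y-linked genes. The renin cell count was 7 to 11, proximal tubule 18 to 19 and thick ascending limb 8 in every setting run for them. The keratin-associated background, the strictest level, was not run for list counts.

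With random lists drawn without receptor and keratin-associated genes, percentiles of list medians moved to 70.6 for the renin-angiotensin system, 79.5 for regulated secretion, 66.5 for prostaglandins, 31.0 for cell cycle, 65.0 for interferon, 19.3 for fibroblasts, 80.7 for endothelium, 53.7 for podocytes, 41.1 for macula densa and 15.3 for adipocytes. The other 31 moved by at most 5 points.

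Of the 27 list shifts outside the central 95% of matched random lists, 17 stayed outside under every alternative counted for them. With all members in place of called ones, 7 came inside: cAMP (percentile 96.9) and Notch (94.65) in replicate 2, Notch (5.19) and immediate early genes (2.55) in replicate 4, and cGMP (81.7), pericytes (73.05) and the distal tubule (91.6) in replicate 5. After quantile normalization 3 did: calcium and angiotensin II in replicate 4 (3.11), and pericytes (95.15) and intercalated cells (94.85) in replicate 5. Without shared members 3 of 25 did: calcium and angiotensin II in replicate 4 (20.25), and cGMP (95.04) and pericytes (97.2) in replicate 5. Against replicate 2 alone, the proximal tubule shift in replicate 5 did (3.81). Otherwise, comparisons with 1 array alone were counted only for endothelial, principal cell and intercalated shifts in replicate 2. Outside that count, replicate 4 against replicate 5 alone lay inside for endothelial (52.95), principal cell (89.63) and intercalated markers (48.0). The endothelial shifts in replicates 4 and 5 and the other 2 in replicate 4 are among the 17. None came inside with centred arrays or with the mean of a gene's probe sets. The pericyte shift in replicate 5 reversed with all members (-0.049). With all members, the shifts in replicate 2 were 0.25 for cAMP, 0.26 for Notch, 0.20 for stromal transcription factors, 0.43 for immediate early genes, 0.29 for mesangial cells, 0.56 for endothelium, -0.52 for principal cells and -0.22 for macrophages. In replicate 4 they were -0.19 for the renin-angiotensin system, -0.12 for stromal transcription factors, 0.036 for interferon, 0.029 for the distal tubule and 0.082 for macrophages. In replicate 5 they were 0.027 for the renin-angiotensin system, -0.19 for cAMP, -0.18 for connexins, 0.057 for regulated secretion, 0.16 for interferon, -0.14 for mesangial cells, -0.33 for endothelium and 0.12 for the distal tubule.

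After quantile normalization, the shifts in replicate 2 were 0.17 for stromal transcription factors, 0.15 for glycolysis, -0.011 for oxidative phosphorylation, -0.29 for interferon, 0.10 for housekeeping, 0.13 for the proximal tubule and -0.10 for the thick limb. In replicate 4 they were -0.12 for stromal transcription factors, 0.14 for lysosome, -0.16 for regulated secretion and 0.22 for the proximal tubule. In replicate 5 they were 0.081 for renin cells, -0.19 for cAMP, 0.043 for Notch, 0.0058 for stromal transcription factors, 0.079 for protein folding, -0.24 for lysosome, 0.14 for hypoxia, -0.15 for glycolysis, -0.12 for oxidative phosphorylation, 0.26 for interferon, -0.12 for immediate early genes, 0.19 for smooth muscle, -0.35 for the proximal tubule, -0.60 for the thick limb and 0.75 for the distal tubule. With arrays centred on their medians, replicate 5 gave -0.24 for protein folding, -0.34 for oxidative phosphorylation, -0.12 for smooth muscle and -0.68 for the proximal tubule, and the mean of a gene's probe sets gave 0.28 for the distal tubule. Without shared members, replicate 4 gave -0.0080 for calcium and angiotensin II and -0.36 for smooth muscle. Against 1 array alone, replicate 2 gave -1.27 (replicate 4) and -0.46 (replicate 5) for principal cells and -0.54 (replicate 4) for intercalated cells. On the second lists, replicate 2 gave 0.63 (replicate 4) for endothelium and -0.61 (replicate 4) and -0.017 (replicate 5) for the collecting duct, and replicate 5 gave -0.71 (replicate 2) for the proximal tubule.

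Among named genes, these called means went under the level at the 99th percentile: Aqp6 (-0.39), Col3a1 (-0.068), Irf1 (-0.22), Kdm5d (-0.17), Lyst (-0.20), Mcm2 (-0.16), Mcm6 (-0.13), Tbp (-0.12), Tyrobp (-0.48) and Vmn2r-ps104 (-0.016). With the mean of a gene's probe sets, Hmcn1 (-1.39) and Irf1 (-0.073) did. A further 38 named genes lost their call at the 99th percentile.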

Other observations

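In the weighing below, the tests against matched random lists and the comparison of endothelial with collecting duct markers were chosen after the shifts were seen, as were those over all measured members of the second lists and those against 1 other array alone, and the 3 patterns were picked from 90 list shifts. The tests on second marker lists were written before those lists' values were looked at. The design holds 1 group, so no explanation by treatment or condition was tested.

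Endothelial markers were 0.77 higher in replicate 2 (0.71 above replicate 4 alone and 0.83 above replicate 5 alone), with Emcn at 9.22 ± 0.56 and Flt1 at 7.58 ± 0.97, and 1 of the 14 markers also stands on another list. An array-wide shift of genes of like signal is argued against, since the list lay at percentile 100 of 10000 matched random lists as deposited and after quantile normalization, and again over all 14 measured markers (0.56), where the called 8 had leaned on that array. A smaller share of the main sorted cells is argued against as the whole cause, since it raises the markers of other cells alike. The endothelial shift exceeded that of principal cells by 1.53 (SD 0.23 over random lists). Over all measured members the shifts were 0.56 and -0.52, and against replicate 5 alone 0.51 and -0.23. A second proximal tubule list was 0.55 higher in replicate 2 as well (20 of 22 measured, percentile 100). A smaller share would also lower the genes of the main sorted cells, and no such fall was seen. Called renin cell genes were 0.31 higher in replicate 2 (9 of 10, percentile 86.03) and smooth muscle genes 0.25 (12 of 14, percentile 88.63). Pericyte genes stood at 0.03 (6 of 9, percentile 22.29). None of these lists lay outside the central range of matched random lists, so a smaller share as part of the cause stays open. A candidate explanation that stays open is more endothelial cells or RNA in that sort, which the YFP gate would remove: a second endothelial list shifted by 0.41 (8 of 9 called members, percentile 99.2) and by 0.38 over all 22 measured, though part of this came from replicate 4, where it lay at -0.42, and its 0.44 above replicate 5 alone lay at percentile 96.4. Immediate early and dissociation genes were 0.66 higher on the same array, and neither cell handling nor a change in gene activity within the sorted cells was tested.

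Proximal tubule markers were lower in replicate 5, by -0.57, and none of the 19 stands on another list. The narrower signal range of that array is argued against as the whole cause, since the list lay at percentile 0.18 of matched random lists, and at 0.11 after quantile normalization, where the shift was -0.35, although against replicate 2 alone it was -0.48 at percentile 3.81, inside the central 95%. A candidate explanation is less proximal tubule RNA in that sort, from cells the YFP gate would remove: a second list of tubule genes shifted by -0.56 (19 of 20 called members, percentile 0.30), and lay lower than replicate 2 alone by -0.71 (percentile 0.04) and than replicate 4 alone by -0.51 (percentile 0.91). Thick ascending limb markers (-0.86, 8 of 8) were lower on the same array, so the fall was not confined to the proximal tubule. The endothelial list was lower there too (-0.53, 7 of 8), but mainly because replicate 2 was high. Its called markers in replicate 4 lay only 0.03 above replicate 5 (percentile 52.95). Single markers did not move alike, with Gpx3 (12.69 ± 0.27) at -0.44 and Gatm at -0.45, but Slc27a2 (12.25 ± 0.15) at -0.05 and Kap (13.09 ± 0.08) at 0.03, so what lies behind the shift stays open.

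Principal cell and intercalated markers were lower in replicate 2, in 15 of 15 called members together, and none stands on another list. Part of this came from replicate 4, where principal cell markers were 0.60 higher (7 of 7): the lists together were lower than replicate 4 alone by -0.65 and than replicate 5 alone by -0.44 (12 of 15 members, percentile 0.0). An array-wide shift of genes of like signal is argued against, since the 2 lists together lay at percentile 0.0, under all 10000 matched random lists, as deposited and after quantile normalization. Candidate explanations are less collecting duct RNA in replicate 2 and more in replicate 4, from cells the YFP gate would remove: a second list shifted by -0.32 in replicate 2 (11 of 12 called members, percentile 0.02) but by -0.017 against replicate 5 alone (6 of 12, percentile 2.53), and over all 20 measured by -0.27 in replicate 2, -0.13 against replicate 5 alone (percentile 1.42) and 0.48 in replicate 4. Set against replicate 5 alone, replicate 4 was 0.21 higher on the 2 first lists together (percentile 67.66). On the second list it was 0.43 higher over called members (percentile 84.88) and 0.39 over all measured (percentile 99.14). Scnn1g was at 7.42, 8.69 and 8.76 in replicates 2, 4 and 5 and Fxyd4 at 8.08, 9.54 and 8.15. Which array stood apart thus differed between genes, and the pattern stays a hypothesis.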
